A study of Mus musculus with 6 samples.

How the data were processed

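Poly(A) RNA of mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, was sequenced at 3 months of age. The libraries fall into 2 groups of 3. The control carries loxP-flanked Kif2a alleles without Cre, and the conditional knockout carries the same alleles together with Cre driven from the advillin gene Avil, which is active in sensory neurons. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

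The authors deposited one table with a row per gene symbol. Its raw counts are whole read counts per gene, per the file headers. The submitters' processing notes name cutadapt, STAR, DESeq2 and the mm10 build; their versions, the program that counted reads and whether counting used strand are not given in the sources used here. The normalized signal in the deposited table is the count divided by a single factor per library, as the values show. The regularized log2 values and the log2 fold changes in the deposited table were made by the authors. The deposited table also gives a p-value per gene and a false discovery rate that the authors computed with fdrtool, per the file headers. No gene in it has fewer than 6 counts over all 6 libraries. Only the raw counts entered the tests below, and the authors' fold changes and rates are quoted as theirs.

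Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 17759 of 22087 genes. Libraries were scaled by TMM, and the groups were compared by a quasi-likelihood F test with robust dispersion estimates and no covariate. Benjamini-Hochberg adjusted p under 0.05 counted as passing. CPM values use the TMM-scaled library totals. Standard errors of log2 fold changes were derived from the F statistic. Single genes were also compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p under 0.1. The total counts per library range from 21683083 to 31626625, and the common biological coefficient of variation was 0.205.

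In simulated counts with the means, dispersions and library sizes of the 17759 genes, for the comparison of conditional knockout with control, the test recovered 11.9% of 67 genes changed 1.5-fold, 47.8% of 67 genes changed 2-fold and 87.9% of 66 genes changed 4-fold. Of its 110 calls there, 12 were false, a share of 10.9% that is above the nominal rate.

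Before the data were examined, 45 gene lists with at least 3 measured members were written from general knowledge of ganglion neurons, glia, other tissues and cell processes. They hold 898 genes, of which 844 were tested and 33 stand in more than 1 list. Each list was compared with all other genes by camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 45 lists. In simulated counts without correlation between genes, camera called 5 of 5 lists of 20 genes shifted by 0.50 on the log2 scale and 0 of 40 unshifted lists. A list score is the mean, over its members, of the log2 deviation from the gene's mean over the 6 libraries.

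The rule for naming genes was also set beforehand. It takes Kif2a and Avil; up to 10 genes in each direction that pass the test, with a mean of at least 1 CPM and no overlap between groups; up to 4 members of smallest p from each list that passes or has a passing member; and up to 3 from the lists of nociceptor classes, TRP and sodium channels, PI3K, injury and neurotrophin signalling. Any other gene named was chosen after its values were seen, and 1 gene that the rule selects is not reported here. Positions and gene types come from GENCODE release M21 on GRCm38 (mm10), matched by symbol, which gave a position for 98.2% of tested genes.

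Alternatives were DESeq2 1.42.0, limma-trend with a pseudocount of 1, 2 other scalings, 3 other filters, a test against a fold of 1.5, the replicate number as a block, each library left out in turn, and camera with an estimated correlation or fry for the lists. A sex term was not fitted, because Y-linked genes were expressed in all 6 libraries. Other pseudocounts were planned only for normalized values and were not run. Added after seeing the data were edgeR with bias-adjusted deviances, removal of a lowess trend (span 0.3) on transcript GC content, and a fit without control replicate 2 and conditional knockout replicate 1.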

Results

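Gene expression in dorsal root ganglia was compared between 3 control libraries and 3 libraries from mice in which Avil-driven Cre targets Kif2a in sensory neurons. Kif2a encodes a kinesin that depolymerises microtubule ends, and the series asks about its part in nociception. The control libraries held 22107327, 22772093 and 31626625 counts, and the conditional knockout libraries held 21683083, 23279155 and 23861941. Correlations of log2 CPM between libraries of one group ranged from 0.965 to 0.988, and no pair agreed within sampling noise. Y-linked Ddx3y had between 1484 and 2116 counts in each library and Xist had between 2 and 9.

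The targeted gene Kif2a (chromosome 13, 106958996 to 107022126, minus strand) was at 86.4, 80.4 and 90.0 CPM in control replicates 1 to 3 and at 69.8, 66.5 and 67.4 CPM in the conditional knockout replicates. The means were 85.6 ± 4.87 and 67.9 ± 1.70 CPM (SD, n = 3), or 79.3% of control. The log2 fold change was -0.33 ± 0.10 (SE), with an unadjusted edgeR p of 0.00920 and an adjusted p of 1.0, so Kif2a did not pass over all genes. The groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest this design allows. In the authors' deposited table its false discovery rate from fdrtool was 0.0408. That rate is not a Benjamini-Hochberg adjusted p, which was 0.634 with DESeq2 on the same counts. Cells of the ganglion other than sensory neurons do not carry the deletion, and reads from exons that are not deleted still count, so the level over the whole gene measures the deletion only in part. The end of Kif2a overlaps Dimt1 on the opposite strand.

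Avil (chromosome 10, 127000709 to 127020994), the gene that drives Cre and encodes an actin-binding protein of sensory neurons, was at 582 ± 17.5 CPM in control and 287 ± 68.7 CPM in the conditional knockout (SD, n = 3), 49.2% of control. Its log2 fold change was -1.02 ± 0.17 (SE) with an edgeR adjusted p of 0.444. With DESeq2 the adjusted p was 5.27e-05, and without conditional knockout replicate 2, which had the highest Avil of its group at 365 CPM, the edgeR adjusted p was 0.0244.

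Over all 17759 genes, 4 fell in the conditional knockout, all 4 by more than 1.5-fold, and 0 rose. Scn2b, an auxiliary subunit of voltage-gated sodium channels, fell from 37.3 ± 6.37 to 11.9 ± 1.95 CPM (SD, n = 3), a log2 fold change of -1.65 ± 0.18 (SE) with an edgeR adjusted p of 0.0270. The other calls were predicted genes. Gm266, annotated as protein coding, went from 2.66 ± 0.103 to 0.205 ± 0.103 CPM, with a log2 fold change of -3.68 ± 0.37 and an edgeR adjusted p of 0.0236. Gm1976, a processed transcript, went from 17.5 ± 1.15 to 6.11 ± 0.566 CPM, with a log2 fold change of -1.51 ± 0.15 and the same adjusted p of 0.0236. Gm40518, a long intergenic RNA, had 657 counts over the control libraries and 1 count over the conditional knockout libraries (edgeR adjusted p 0.00116). That is 0.169% of the control level, with an exact 95% counting interval from 0.00428% to 0.946% that covers counting error only. Scn2b, Gm266 and Gm1976 overlap other annotated genes, and without strand in the counting their reads cannot be fully told apart.

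The edgeR count of 0 genes that rose stands beside 280 genes higher and 549 lower at an unadjusted p under 0.05. Together these are 829 of 17759 genes, a share under the 0.05 that chance alone would give. DESeq2 called 28 genes, 7 higher and 21 lower. The groups did not overlap for 8.66% of genes, where chance gives 10%. The number of calls hung on single libraries: it was 1 without control replicate 1, 1 without control replicate 2, 10 without conditional knockout replicate 1, 13 without replicate 2 of that group and 0 without its replicate 3. With the replicate number as a block it was 0. Scn2b missed the threshold without any 1 of the control libraries (edgeR adjusted p 0.0654, 0.147 and 0.101) and without conditional knockout replicate 3 (0.257), and Gm266 and Gm1976 missed it without the same libraries. Gm40518 missed it without conditional knockout replicate 3 (0.0579). Without control replicate 3 the count was 3, with 2 of them higher. In the authors' deposited table, 145 genes carry the mark for passing both their false discovery rate and a fold of 1.5, with 52 higher and 93 lower. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table leaves 26 genes, and 60.6% of those p-values lie above 0.5. Of the 145 marked genes in the authors' deposited table, 131 were tested here and all 131 had the same direction. Both sets of fold changes come from the same counts, so this shared direction is no separate support.

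**Figure D1:**
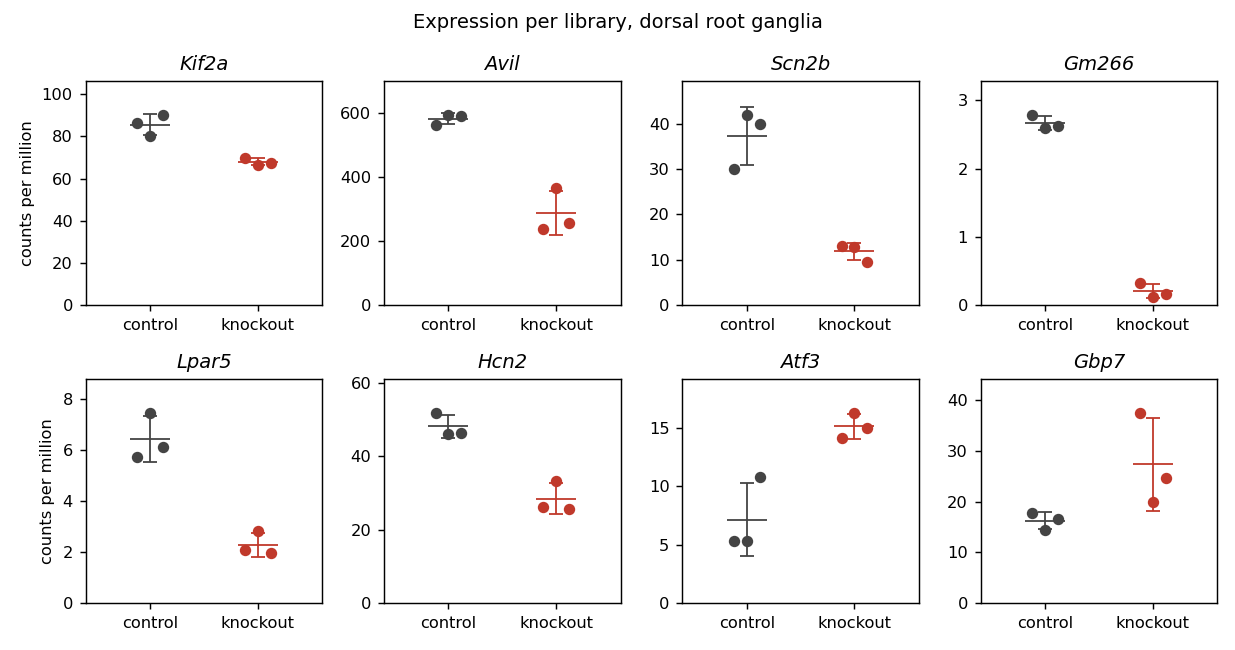
CPM of 8 genes in each library, with points for libraries, a horizontal line for the mean and bars for the SD (n = 3), on linear axes from 0. Kif2a lies at 67.9 CPM in the conditional knockout against 85.6 CPM in control, while Scn2b lies at 11.9 against 37.3 CPM.

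Among the fallen genes, Scn2b (chromosome 9, 45117782 to 45130070) and Gm40518 (chromosome 9, 48132504 to 48158965) are 3.00 Mb apart. Gm266 lies on chromosome 12 (111484609 to 111485823) and Gm1976 on chromosome 17 (94759944 to 94834799). None of these chromosomes carries Kif2a or Avil.

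**Figure D2:**
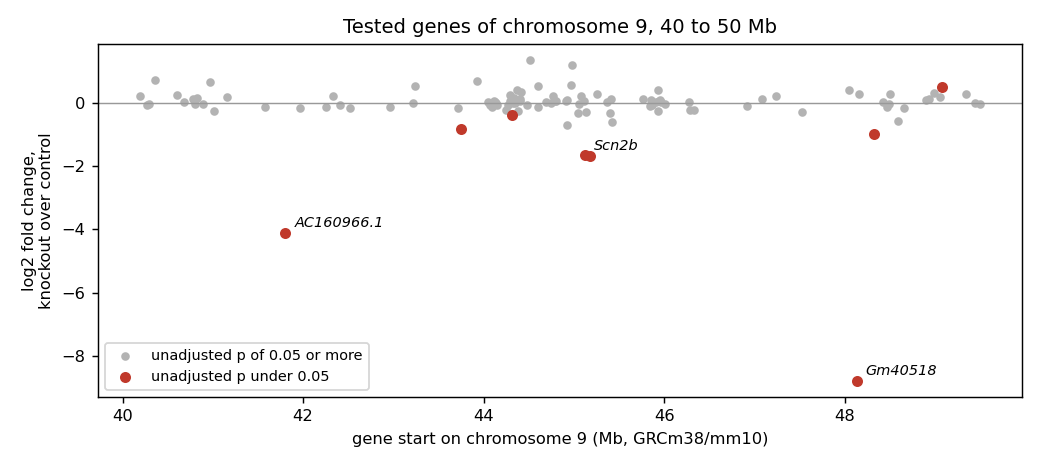
Log2 fold change of conditional knockout over control against gene start in Mb on a stretch of chromosome 9 (GRCm38/mm10), a point per tested gene, red for an unadjusted p under 0.05. Scn2b at -1.65 and Gm40518 at a fitted -8.78 lie below most of their neighbours; the fitted value of Gm40518 rests on 1 count in the conditional knockout and depends on the prior count.

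The 2 lists of nociceptor classes moved apart. The non-peptidergic list, which holds receptors and channels of pain and itch neurons classed apart from the peptidergic nociceptors, fell. In it 16 of 18 members were lower, with a median log2 fold change of -0.54 and a camera adjusted p of 3.79e-10. That call is lost with an estimated correlation between genes (adjusted p = 0.831). Of its members 0 passed over all genes, and 11 passed adjusted over the list alone. Lpar5, a lysophosphatidic acid receptor, was at 6.45 ± 0.899 CPM in control and 2.28 ± 0.463 CPM in the conditional knockout (SD, n = 3), or 35.5% of control, with an adjusted p of 0.331 in edgeR and 9.92e-05 in DESeq2. Lpar3 was at -0.75 ± 0.22, the Mas-related receptor Mrgprb5 at -0.66 ± 0.18 and the leukotriene receptor Cysltr2 at -0.57 ± 0.17 on the log2 scale. The list score was -0.29, -0.18 and -0.31 in the conditional knockout libraries and -0.03, 0.47 and 0.35 in control. The peptidergic list, the neuropeptide-bearing nociceptors, rose by less: 11 of 13 members were higher, with a median of 0.20 and a camera adjusted p of 0.0175. The call is lost with an estimated correlation (adjusted p = 0.831), and 0 members passed adjusted over the list alone. Its members of smallest p were Adcyap1, the neuropeptide PACAP, at 0.32 ± 0.11, Tafa1 at 0.35 ± 0.14, Gfra3 at 0.23 ± 0.13 and Bmpr1b at 0.32 ± 0.19. The peptidergic call was lost too without control replicate 1 (adjusted p 0.0544), without conditional knockout replicate 1 (0.0778) and without its replicate 2 (0.0631). With each library left out in turn, the non-peptidergic median ranged from -0.67 to -0.40 and the peptidergic median from 0.14 to 0.27. Gfra3 was at 0.35 without control replicate 1, and Bmpr1b at 0.19 without control replicate 3.

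**Figure D3:**
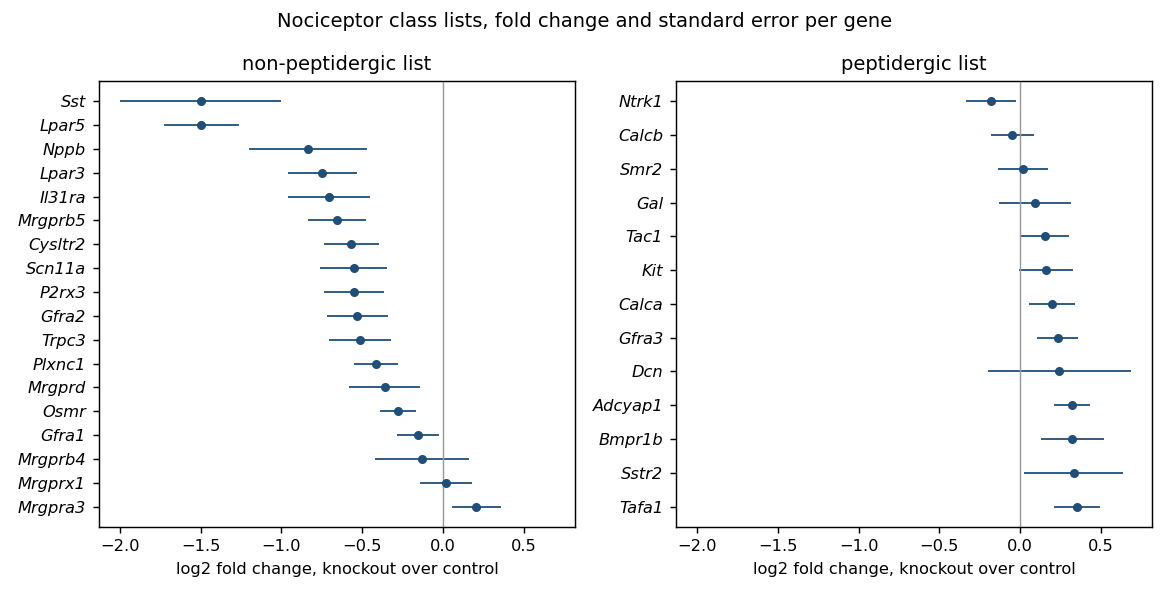
Log2 fold change of conditional knockout over control for each measured member of the non-peptidergic list (18 genes) and the peptidergic list (13 genes), with bars for the standard error. Non-peptidergic members lie mostly below 0, with a median of -0.54, and peptidergic members mostly above, with a median of 0.20.

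The lists of the nerve terminal, of potassium and HCN channels and of axonal transport were lower. Of 28 synaptic vesicle and terminal genes 22 were lower, with a median of -0.21 and a camera adjusted p of 0.000654, a call lost with an estimated correlation (adjusted p = 0.831). The vesicle proteins Syn1 at -0.63 ± 0.16, Vamp2 at -0.46 ± 0.17 and Syp at -0.45 ± 0.17 and the active zone protein Bsn at -0.42 ± 0.13 had its smallest p. In the list of potassium and HCN channels 20 of 29 members were lower, with a camera adjusted p of 0.0134, a call lost with an estimated correlation (adjusted p = 0.831). Its pacemaker channel Hcn2 passed adjusted over the list alone, at 48.1 ± 3.20 CPM in control and 28.4 ± 4.25 CPM in the conditional knockout (SD, n = 3), a log2 fold change of -0.76 ± 0.13. Over all genes its adjusted p was 0.448 in edgeR, 0.00569 in DESeq2 and 0.0486 in edgeR without conditional knockout replicate 2. Kcnn1 was at -0.39 ± 0.12, Kcnj10 at -0.31 ± 0.12 and Kcnt2 at 0.53 ± 0.20. The list of kinesin and dynein transport was lower in 17 of 22 members (adjusted p 0.0256, and adjusted p = 0.831 with an estimated correlation, which ends the call), among them Klc2 at -0.46 ± 0.18, Dctn1 at -0.44 ± 0.17, Kif1a at -0.38 ± 0.17 and Kif5a at -0.42 ± 0.20. These 3 calls are also lost without conditional knockout replicate 1, with adjusted p of 0.529 for the terminal, 0.577 for potassium and HCN channels and 0.567 for transport. The channel and transport calls were lost as well without control replicate 1 (0.154 and 0.162) and without conditional knockout replicate 3 (0.119 and 0.136). The medians moved with single libraries. Without conditional knockout replicate 1 the terminal median was -0.052, the transport median, -0.09 over all libraries, was -3.9e-05, and that of the potassium and HCN list turned from -0.12 to 0.022. Without its replicate 2 they were -0.37, -0.17 and -0.27, and without its replicate 3 the transport median was -0.017 and the channel median -0.049. Klc2 was at -0.31 without replicate 1, and Kif5a at -0.69 without replicate 2 and -0.27 without replicate 3. The 3 lists were low in conditional knockout replicates 1 and 3 and not in replicate 2: their scores were -0.30, 0.12 and -0.11 for the terminal, -0.25, 0.17 and -0.17 for potassium and HCN channels and -0.18, 0.14 and -0.16 for transport. Replicate 2 was above each control library for the channel and transport lists and above 2 of the 3 for the terminal. In the same libraries the scores of immune lists went the other way, with 0.77, -0.36 and 0.36 for interferon-stimulated genes, 0.79, -0.65 and 0.40 for antigen presentation and 0.87, -0.83 and 0.67 for lymphocyte markers.

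Sodium channels, TRP and related sensory channels and neurotrophin signalling did not pass as lists. Sodium channels had 8 of 12 members lower (adjusted p 0.0583), and besides Scn2b they included Scn11a at -0.55 ± 0.21, while Scn3a was at 0.33 ± 0.16. TRP and related channels had 14 of 20 members lower (adjusted p 0.103), with Trpc6 at -0.49 ± 0.12, the irritant receptor Trpa1 at -0.39 ± 0.12 and the ATP-gated P2rx3 at -0.55 ± 0.19. Neurotrophin and GDNF signalling had 13 of 18 members lower (adjusted p 0.219), with Gfra2 at -0.53 ± 0.19 and Ret at -0.46 ± 0.19. Without conditional knockout replicate 2, Scn3a was at 0.22 and Ret at -0.69. Scores of conditional knockout replicates 1 to 3 were -0.32, 0.16 and -0.19 for sodium channels. For TRP and related channels they were -0.19, 0.14 and -0.12. In both lists replicate 2 was above each control library.

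The PI3K and phosphoinositide list passed with a small shift, 24 of 31 members lower, a median of -0.10 and a camera adjusted p of 0.00265, a call lost with an estimated correlation (adjusted p = 0.831). Its members of smallest p were the kinase Gsk3a at -0.41 ± 0.12, the transcription factor Foxo3 at -0.36 ± 0.12, Irs2 at -0.32 ± 0.12 and Pip5k1c at -0.40 ± 0.16. The axon degeneration and pruning list was lower in 15 of 24 members (adjusted p 0.0464, and adjusted p = 0.831 with an estimated correlation, which ends the call), with the NAD synthesis enzyme Nmnat3 at -1.38 ± 0.36 (1.22 CPM in control and 0.462 in the conditional knockout), the protease Capn1 at -0.48 ± 0.15 and App at -0.33 ± 0.16. The injury and regeneration list was higher in 17 of 26 members (adjusted p 0.0488), a call lost with an estimated correlation (adjusted p = 0.831). Its injury marker Sprr1a passed adjusted over the list alone, at 0.491 ± 0.386 CPM in control and 2.42 ± 0.684 CPM in the conditional knockout (SD, n = 3), with an adjusted p over all genes of 0.825 in edgeR and 0.0221 in DESeq2. The transcription factor Atf3 was at 1.08 ± 0.28 and Ecel1 at 1.27 ± 0.48, while the growth cone protein Basp1 was at -0.40 ± 0.12 on the log2 scale. The PI3K call was also lost without conditional knockout replicate 1 (0.0555) or 3 (0.0585), and its median was -0.173 without replicate 2 and -0.055 without replicate 3. The degeneration call was lost without control replicate 1 (0.0544) or 3 (0.0946), without conditional knockout replicate 1 (0.260) or 3 (0.227), at a mean of at least 5 CPM (0.286) with the replicate number as a block (0.0579) and with a GC trend removed (0.0627). Its median, -0.10 over all libraries, was -0.028 without control replicate 3 and -0.017 without conditional knockout replicate 3, where App was at -0.18. The injury call was lost without control replicate 1 (0.203), without conditional knockout replicate 1 (0.0929), 2 (0.250) or 3 (0.0858), at a mean of at least 5 CPM (0.254) and with DESeq2 size factors (0.0507). Its median, 0.08 over all libraries, was 0.042 without control replicate 1, 0.15 without control replicate 2 and 0.13 without conditional knockout replicate 1, and Ecel1 was at 2.09 without control replicate 3.

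Interferon-stimulated genes were the list with the smallest p, higher in 29 of 30 members with a median of 0.65 and a camera adjusted p of 1.72e-10, a call lost with an estimated correlation (adjusted p = 0.831). The list members Gbp7 at 0.75 ± 0.22, Ifit1 at 0.50 ± 0.17, Rtp4 at 0.82 ± 0.28 and Xaf1 at 0.44 ± 0.16 had the smallest p. Of all members 0 passed adjusted over the list alone. The score was 0.77 and 0.36 in conditional knockout replicates 1 and 3 but -0.36 in replicate 2, below the control libraries at -0.29, -0.27 and -0.22. Antigen presentation (16 of 17 members higher, adjusted p 0.00717), lymphocyte markers (13 of 14, adjusted p 0.0116) and endothelial markers (12 of 14, adjusted p 0.0120) also passed. These 3 calls too are lost with an estimated correlation (adjusted p = 0.831 for each). Their scores put conditional knockout replicate 2 at -0.65, -0.83 and -0.19 and replicate 1 at 0.79, 0.87 and 0.46. Examples were H2-Q7 at 1.36 ± 0.62, B2m at 0.80 ± 0.41, Cd3d at 1.20 ± 0.60 (0.565 CPM in control and 1.29 in the conditional knockout) and Slco1a4 at 0.44 ± 0.14. Without conditional knockout replicate 1 the interferon median was 0.32, with Gbp7 at 0.46 and Rtp4 at 0.54. The antigen presentation median, 0.50 over all libraries, was 0.12 without that library and 0.85 without replicate 2, and the lymphocyte median, 0.59 over all libraries, was 0.25 and 0.97 in the same fits and 0.33 without control replicate 1. The endothelial median was 0.33 without replicate 2. B2m was at 0.53 without conditional knockout replicate 3, and Cd3d at 0.73 without that library and 2.09 without control replicate 2. Without conditional knockout replicate 2, B2m passed over all genes (edgeR adjusted p 0.0323). Without conditional knockout replicate 1 the adjusted p was 0.804 for antigen presentation, 0.529 for lymphocytes and 0.858 for endothelium, whose median turned from 0.17 to -0.024. Other libraries also ended these calls when left out: control replicate 1 for antigen presentation (0.0811), lymphocytes (0.417) and endothelium (0.0602), control replicate 2 for endothelium (0.115), and conditional knockout replicate 3 for antigen presentation (0.0821) and lymphocytes (0.223). The lymphocyte call was lost as well at a mean of at least 5 CPM (camera adjusted p 0.0653).

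Markers of tissue around the ganglion also differed between libraries. Spinal cord and brain markers were lower in 9 of 12 members (median -0.56, adjusted p 0.000799), a call lost with an estimated correlation (adjusted p = 0.831). Members of smallest p were the water channel Aqp4 at -0.90 ± 0.27, Agt at -0.45 ± 0.18, Slc6a5 at -2.29 ± 0.92 and Slc1a2 at -1.54 ± 0.60. Control replicate 2 scored 0.99 for this list. Skeletal muscle genes were lower in 10 of 15 members (adjusted p 0.00181), a call lost with an estimated correlation (adjusted p = 0.831). Its scores were 1.94 in control replicate 3, 1.87 in conditional knockout replicate 1 and -2.34 and -1.88 in its replicates 2 and 3. Myh2 was at -2.84 ± 1.17, with 1.35 CPM in control and 0.195 in the conditional knockout, and Ttn at -1.61 ± 0.98. Without control replicate 3 they were at -1.28 and -0.72, and without conditional knockout replicate 1 at -4.35 and -3.0. Without control replicate 2, Slc1a2 was at -0.70, Slc6a5 at -1.35 and Agt at -0.27, and the median of the spinal cord and brain list was -0.18. That median was -0.87 without control replicate 1, -0.98 without control replicate 3 and -1.04 without conditional knockout replicate 1. The muscle call was also lost without control replicate 3 (0.0946) or conditional knockout replicate 2 (0.198). The median of the muscle list, -0.20 over all libraries, turned to 0.21 and 0.11 in those fits, and to 0.057 without conditional knockout replicate 3, where the set test still pointed down; it was -0.34 without control replicate 1, -0.38 without control replicate 2 and -3.42 without conditional knockout replicate 1.

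**Figure D4:**
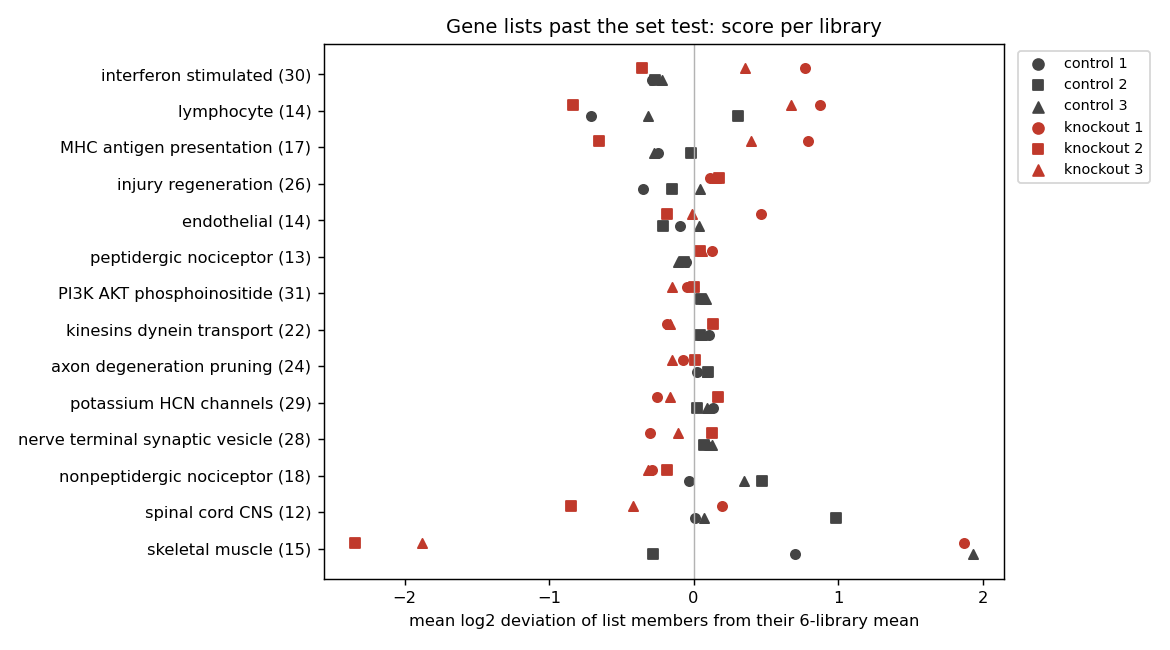
Score of each of the 14 lists that passed the set test, in each of the 6 libraries, as the mean log2 deviation of the members from their mean over all libraries, with the number of measured members in brackets. Skeletal muscle spans from -2.34 to 1.94, while the peptidergic and PI3K lists stay close to 0.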

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

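The removal of a GC trend, the bias-adjusted deviances and the fit without 2 libraries were chosen after seeing the data. The count of 4 changed genes was also 4 with limma-trend, both other scalings, no filter, a minimum count of 5, bias-adjusted deviances and the GC trend removed, and all 4 genes were shared each time. It was 28 with DESeq2 (7 higher, 21 lower, with 5592 adjusted p not given), 2 at a mean of at least 5 CPM, which tests fewer genes, 1 against a fold of 1.5, and 25 without control replicate 2 and conditional knockout replicate 1, where all 25 were lower. Leaving out each library gave 0 to 13 genes. With the replicate number as a block the count was 0. Same-numbered libraries deviated apart (correlations of -0.15, -0.25 and -0.13), which gives no sign of pairing. With 3 libraries per group this cannot exclude a pairing by litter or handling. Apart from the tests' own construction, the cause of the differing counts was not tested.

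Of 45 lists, 14 passed. The count was 0 with an estimated correlation, 1 with fry's directional test (the peptidergic list) and 0 with its mixed test, 9 without the 2 libraries, and 6 to 26 with each library left out; the block gave 14 and lost the degeneration list. Kif2a stayed below control in every fit, from -0.29 to -0.40, with no adjusted p under 0.05 (lowest 0.250). With each library left out, Myh1 ranged from -2.22 to 0.056 and Neb from -0.97 to 0.34, both positive only without control replicate 3, and the endothelial median turned to -0.051 without the 2 libraries. With each library left out, list medians ranged from -3.42 to 0.21 for muscle (positive without control replicate 3 or conditional knockout replicate 2 or 3), from -0.024 to 0.33 for endothelium (negative without conditional knockout replicate 1) and from -0.27 to 0.022 for potassium and HCN channels (positive without the same library). The cause of these turns was not tested. Of the named genes' other values, 1118 kept their side of the threshold, 17 lost and 7 gained it. Only a gene that had passed could lose it, and all 17 losses fell on Scn2b, Gm266, Gm1976 and Gm40518. Most of the 1118 belong to genes that had not passed to begin with, so they are no measure of stable calls. Low counts limit Gm266, Slc6a5, Sprr1a, Nmnat3, Myh1, Myh2 and Cd3d, at under 3 CPM in both groups.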

Other observations

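All tests of explanations below were chosen after the results were seen, including the counts of other splits. Lists not yet described did not pass. Ribosomal protein genes were higher in 54 of 59 members with a median of only 0.07 (camera adjusted p 0.489), cholesterol and lipid synthesis in 17 of 25 (0.0655), cytokines and chemokines in 15 of 20 (0.180), macrophage markers in 16 of 20 (0.458), and immediate early genes in 15 of 21 (0.290). Myelinating Schwann cell genes were lower in 13 of 20 (0.458), cartilage and bone markers in 6 of 7 (0.0510), and touch and proprioceptive neuron genes in 10 of 17 (0.346). Satellite glia markers had a median of 0.05 (0.524). Adipocyte and fibroblast lists had positive medians of 0.14 and 0.10 while their set test pointed down (0.489 and 0.775), and transmitter and opioid receptors had a median of 0.03, a mean of -0.03 and a test pointing down (0.689).

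The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4 genes and the highest of the others 3, so 1 of the 10 splits gave as many. For lists, 7 of the 10 splits, the real one among them, gave at least as many as the real 14. The highest of the others gave 27, so the number of called lists does not set the genotype split apart. Why other splits called so many lists was not tested. The real split had the smallest p of the 10 for the non-peptidergic, peptidergic and PI3K lists, and not for the other called lists. It also did for the uncalled list of the kinesin family of Kif2a. That list has 3 measured members, of which Kif2a, the targeted gene, is 1, so it says little about the family. Chance alone would put the real split first for about 1 list in 10, so this rank does not set these lists apart.

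Genes low in the conditional knockout lay close together. Among the 20 genes of smallest p, 18 were lowered and 5 of these formed 3 pairs within 5 Mb, on chromosome 9 (AC160966.1, Scn2b and Gm40518) and chromosome 12 (A230087F16Rik and Gm266). Flanking DNA of the targeted loci is argued against, since 0 of the 5 lie within 10 Mb of Kif2a or Avil. Chance placement stays open, as a share of 0.0531 of 100000 random draws held as many pairs; a first version that also counted the risen Ighg2c gave 0.00706 and was replaced because the pattern is about lowered genes. A segment of other strain origin or an insertion may also account for it. Over both chromosomes pooled, 20 of 252 other genes within 5 Mb had an unadjusted p under 0.05. That is 7.94% against 4.53% elsewhere (two-sided Fisher's exact p 0.0149, and 0.0224 in the first version), although neighbouring genes are not independent. The share was not split by chromosome, so it does not show a segment or insertion at either place. The chromosome 9 stretch from Zfp202 to Ncam1 holds AC160966.1, Scn2b and Gm40518. Its only other genes under 0.05 were Nectin1, C2cd2l, BC049352 and Nxpe2, which were lower, and Tmprss5, which was higher.

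Avil was near the level that loss of output from a single allele would give. A lower share of neurons is argued against as the whole cause, since the synaptic vesicle list had a median log2 fold change of -0.21. The Avil value of -1.02, with a 95% interval from -1.41 to -0.63, holds the -1 expected if Cre silences the allele it sits in, which may account for the fall. The expectation assumes that Cre is inserted in 1 Avil allele, which was not checked. The interval is wide, and an effect of losing Kif2a on Avil was not tested.

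The non-peptidergic list was lower while the peptidergic list was higher. A lower share of all neurons alike is argued against as the whole cause. The peptidergic score without Dcn, a gene also of fibroblasts, was 0.16 ± 0.04 (SE) higher in the conditional knockout. Its exact two-sided permutation p was 0.1, the smallest this design allows. That score cannot test a lower share of non-peptidergic neurons alone. A lower share of neurons as part of the cause stays open, as the terminal, channel and transport lists were low in conditional knockout replicates 1 and 3. A GC trend is argued against as the whole cause, since the median of the list was -0.52 once it was removed. Ganglia from other spinal levels cannot be told apart from the genotype: the caudal minus rostral Hox score differed by 0.28 ± 0.33 (SE), within the spread of the libraries. An effect of losing Kif2a on these neurons may also remain, found and tested on the same 6 libraries. Since the control carries no Cre, such an effect cannot be told apart from one of Cre or of lower Avil. The same holds for every other difference between the groups.

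Some values stood out in single libraries, in genes chosen after their values were seen. Pbsn had 982 counts, Svs3a 120 and 9530053A07Rik 8341 in control replicate 3, against at most 8, 0 and 133 in any other library. The mitochondrial gene mt-Atp6 had 747 counts in conditional knockout replicate 1 and at most 1 elsewhere. The antibody gene Ighg2c differed in another way, as it was higher in each conditional knockout library than in any control library. It was at 1.55, 1.36 and 4.04 CPM in control and 10.8, 13.1 and 13.7 CPM in the conditional knockout (edgeR adjusted p 0.448).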
